A study of Mus musculus with 2 samples.

How the data were processed

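Cultured mouse lung fibroblasts were measured in 2 single-cell libraries, 1 control and 1 stimulated, prepared with a droplet 3′ kit, per the labels. The authors deposited, for each library, a sparse matrix of counts, that is, UMI counts per gene and barcode with no normalization, together with its gene and barcode lists. Per the file headers the matrices were written by Cell Ranger 3.0.2, while the submitters' processing notes name Cell Ranger 1.3.1 and Seurat 3.0.0; which of these made the counts was not settled. The genome build, the annotation and the filter that chose the barcodes are not given in the sources used here. Genes are listed by Ensembl identifier and symbol, 27998 in all, and 56 symbols occur more than once. No genome coordinates are printed because the build is not stated. The groups come from the sample titles. The labels state that control cells came from the same lung.

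The deposited counts of both libraries were read as they stand. Barcodes were kept with at least 500 genes and at most 20% of UMIs in the 13 mitochondrial genes, which left out 269 control and 212 stimulated barcodes for few genes and 44 and 18 for mitochondrial UMIs. Deposited barcodes held at least 500 and 504 UMIs, and kept cells 88573140 and 117193148 UMIs in all. The median share of mitochondrial UMIs was 1.36% in the control and 1.07% in the stimulated library. Scrublet as implemented in scanpy 1.11.5, run per library, marked 1 and 0 cells, under the 0.5% set as the least a working caller should mark, so no cell was left out as a doublet and doublets remain in the data. For 1 alternative the cells with the highest Scrublet scores were left out instead, 201 control and 474 stimulated cells.

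Cells of both libraries were clustered together without integration with scanpy 1.11.5 in Python 3.11.15: counts scaled to the median depth and log transformed, 2000 variable genes standardised per gene, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 0.5. A cluster took the name of a cell type other than fibroblast if at least 3 of that type's markers were seen in at least 25% of its cells and at least 2 were among its 10 leading genes. It was fibroblast-like if at least 3 fibroblast markers were seen and no other type led it. Leading genes were ranked by fold against the other cells of the library that holds most of the cluster. A cluster whose median depth was far under its library's, by a factor of over 3, was left unnamed unless one of its markers was among those genes. The marker lists were fixed before the data were examined, and the rule that turns them into names was settled after a first clustering.

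For the comparison of genes, counts were summed over the kept cells of each library and divided by the library total, giving CPM. The fold of a gene is the stimulated CPM over the control CPM, with an exact conditional-Poisson 95% interval. A library without a UMI of a gene was set at 3 counts, so that the fold is a bound. Genes with a mean of at least 5 CPM were compared, and a list's members counted as higher or lower at 1.5-fold. A list's median log2 fold was placed among the medians of 10000 random lists matched on expression in 20 bins. Lists with under 5 measured members got no percentile. The interval of a list median is an order-statistic 95% interval over its members, and for a list of 5 to 8 measured members it is their full range. The comparison used 31 program lists and 12 cell type lists, all fixed before the data were examined, as were the filters and statistics. Named genes were chosen by a fixed rule: the 12 largest folds each way among genes with a mean of at least 25 CPM, leaving out mitochondrial and ribosomal protein genes and symbols of unnamed gene models, where the fold in fibroblast-like clusters was at least 1.5 the same way; the 3 most abundant members of each list and the member with the largest fold; the genes of the share-of-cells comparison; and the 5 largest CPM differences each way. Some genes that this rule selects are not reported here. Other genes named in the text were picked after their values were seen, as stated there.

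Shares of cells, program sums and cycling cells were computed after thinning each cell to 5000 UMIs without replacement, with exact binomial intervals. To find genes that share reads with near copies, the last 400 nt of each transcript of the GENCODE M21 annotation was cut into 90 nt windows every 30 nt and aligned to all transcripts with minimap2 2.31, and windows that matched another listed gene with at most 2 mismatches counted as shared. Of the listed genes 98.6% had a transcript there. The annotation used by the authors may differ from it.

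The fold and list statistics were tested on simulated libraries drawn from the control library's means for 8756 genes, of which 200 were changed. For true folds of 0.25, 0.5, 0.667, 1.5, 2 and 4, with 33 or 34 genes each, the 95% interval covered the true value in 90.9%, 87.9%, 93.9%, 97.1%, 97.1% and 90.9% of genes, and for the 8556 unchanged genes in 95.0%. A list of 20 simulated changed genes stood at percentile 100, and 95 of 100 lists of unchanged genes stood between the 5th and the 95th percentile. The counts were independent Poisson draws for each gene. They thus cover counting error alone, and not variation between libraries or lists whose members move together.

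Alternatives changed 1 setting at a time, except that the one without an expression filter also added 0.5 CPM to both libraries. The expression filter was applied anew to each alternative's own CPM, so the genes and list members compared could change as well. Without mitochondrial and ribosomal protein genes, 9707 genes were compared, against 8787 in the main comparison. Scalings were TMM (edgeR 4.0.16 in R 4.3.3), median of ratios, and CPM without mitochondrial and ribosomal protein genes. Cell sets were all barcodes, stricter cells (at least 1000 genes, at most 10% mitochondrial UMIs), fibroblast-like clusters only, and cells not in cycle only. Others were each cell weighted equally, other expression filters, thinning to 3000 or 8000 UMIs, other cycling thresholds and other clusterings. Added after the data were seen were comparisons without macrophage-like and shallow clusters, between 4 pairs of matched clusters, and without genes whose 3′ end is at least 50% shared. TMM scaling moved all log2 folds by 0.10, which is too small a shift to turn the direction of any fold past 1.5.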

Results

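Cultured lung fibroblasts from C57BL/6 mice, a common inbred strain, were profiled by droplet single-cell RNA sequencing of transcript 3′ ends, in which each molecule carries a unique molecular identifier (UMI). The labels give 2 libraries, 1 per group: a control library from cells kept with vehicle, and a library from stimulated cells. Cells were stimulated at passage 3 for 14 days. The culture protocol lists 10 µM rosiglitazone (a PPARG agonist), 1 µM SB4315442 and 4 µM rhBMP4 (recombinant human bone morphogenetic protein 4), used singly or combined, and the labels do not say which of them the stimulated library received. They also name a medium supplement, ITS+3 at 1% by volume, as a way to induce a lipofibroblast-like state, that is, fibroblasts that store lipid in the alveolar wall. The control library held 5016 barcodes and 88876791 UMIs, and the stimulated library 7698 barcodes and 117381412 UMIs. After filtering, 4703 control and 7468 stimulated cells were kept, with a median of 19634 and 15379.5 UMIs per cell. With 1 library per group there is no replicate check, so no test across samples was possible. All intervals are 95% intervals, and those of folds and of shares of cells cover counting error only. Intervals of list medians and of shares of genes are taken over genes, and that of a median measures the spread between members.

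Most cells of both libraries were fibroblast-like. Joint clustering gave 14 clusters, and the fibroblast-like ones held 80.2% of control cells (exact binomial interval 79.0 to 81.3%) and 82.8% of stimulated cells (82.0 to 83.7%). Every fibroblast-like cluster but 1 came almost wholly from a single library, so clusters stand for libraries as much as for cell states and their sizes were not compared. The exception was a small cluster with the stress genes Ddit3 and Trib3 among its leading genes, with 77 control and 213 stimulated cells. A macrophage-like cluster with 11 of 12 macrophage markers detected held 150 control cells, 3.19% of that library (2.71 to 3.73%), and 1 stimulated cell, 0.013% (0 to 0.075%). Mesothelial-like cells made up 1.28% of the control library (0.975 to 1.64%) and 0.308% of the stimulated library (0.195 to 0.462%). Unnamed clusters held 15.4% of control and 16.8% of stimulated cells. Most of these were shallow, but 1 unnamed cluster of 541 stimulated cells, 7.24% of that library against 0.043% of the control, had a smooth muscle marker, Des, among its leading genes, which kept it out of the fibroblast-like class. Its closest control counterpart, a cluster of 387 cells, is in that class, so the fibroblast-like sets of the libraries differ in make-up, and values from fibroblast-like cells alone carry this limit.

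The first question was which genes differed between stimulated and control fibroblasts. Of 8787 genes with a mean of at least 5 counts per 1e6 UMIs (CPM), 290 were at least 2-fold higher and 444 at least 2-fold lower in the stimulated library. Among genes with a mean of at least 25 CPM that the naming rule covers, the serine protease inhibitor gene Serpina3n showed the largest fold higher. It was at 694 CPM against 9.92 CPM, 69.9-fold higher (65.4 to 74.8). Serpinb2 was 30.9-fold higher (26.2 to 36.6), and Il1rn, which encodes the interleukin 1 receptor antagonist, 15.6-fold higher (14.2 to 17.1). Col15a1 (13.3-fold), Fabp4 (12.2-fold), the matrix metalloproteinase gene Mmp3 (10.6-fold), the retinaldehyde-oxidising enzyme gene Aldh1a1 (9.22-fold), Spp1 (8.74-fold) and Fkbp5 (7.71-fold) followed. Hist1h2ap and Nme2 were also among the 12 largest folds, at 14.7-fold and 11.6-fold higher. At least 95.5% of the 3′ end windows of both genes match another listed gene, so their folds are uncertain.

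Macrophage genes led the largest folds lower in the stimulated library among genes with a mean of at least 25 CPM, followed by genes of several kinds. Tyrobp, Lyz2, C1qb, Wfdc17 and Fcer1g, genes of macrophages and related cells, were 1582, 716, 527, 338 and 264-fold lower. These genes mark the macrophage-like cells seen almost only in the control library, and 54.5% of the 3′ end windows of Lyz2 match another gene. At 5000 UMIs per cell 15.4% of control fibroblast-like cells also carried a Lyz2 UMI, against 0.197% of stimulated fibroblast-like cells. Igf1, the insulin-like growth factor 1 gene, was 37.2-fold lower (34.1 to 40.6), with 169 CPM in the control and 4.54 CPM in the stimulated library. The skeletal actin gene Acta1 was 36.8-fold lower (33.0 to 41.2) and Wisp2 34.5-fold lower (32.7 to 36.5). The acute phase gene Saa3 (24.5-fold), the natriuretic peptide clearance receptor gene Npr3 (23.5-fold), the proteoglycan gene Dcn (20.9-fold) and the chemokine gene Cxcl14 (17.1-fold) were lower as well. In fibroblast-like cells alone, with the limit given above, Npr3 was 64.9-fold and Cxcl14 29.3-fold lower, and matched clusters differed. The log2 fold of Cxcl14 was -1.65, -2.20 and -2.22 in clusters 2 and 0, 3 and 1, and 4 and 7. These pairs leave out control cluster 9, where Cxcl14 is a leading gene, so they do not bound its fold. In clusters 9 and 6 the log2 fold of Npr3 was -2.36 and that of Saa3 -2.10. In absolute terms Mt1, Fth1, Mt2, Mgp and Gm10076 gained most in CPM and Sparc, Rpl41, Ftl1, Tmsb4x and Thbs1 lost most. The metallothionein gene Mt1 was at 14730 CPM against 3114 CPM, and the ferritin heavy chain gene Fth1 at 15570 CPM against 5352 CPM. Ftl1 and Gm10076 share at least 95.5% of their 3′ end windows with other genes, and Rpl41 61.4%.

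**Figure D1:**
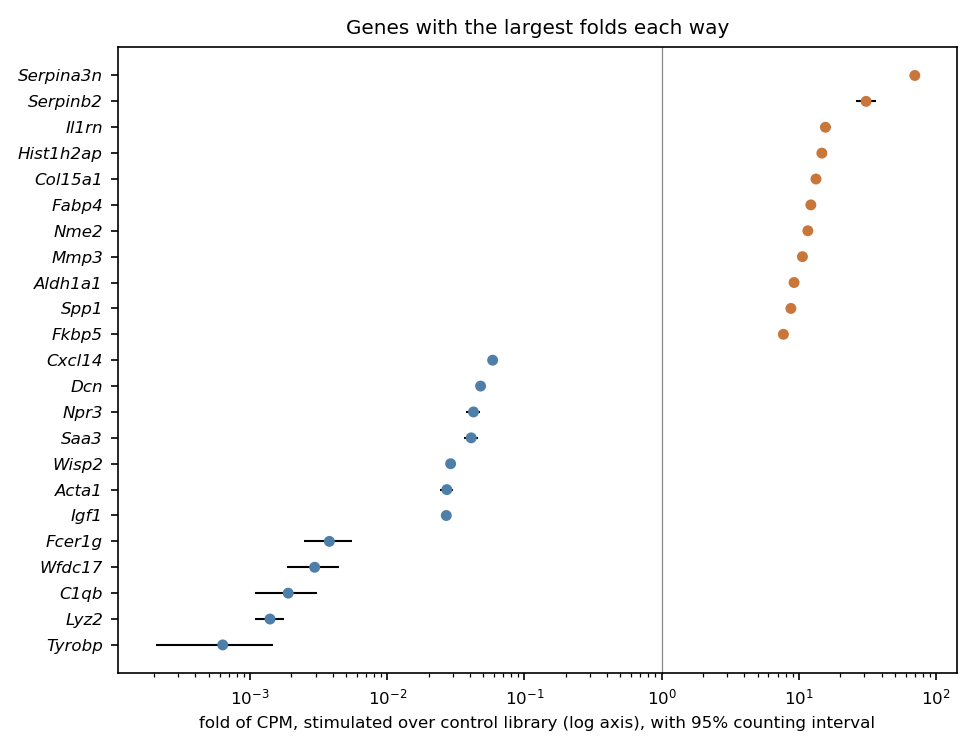
Fold of CPM, stimulated over control library, on a log axis for genes with the largest folds each way; points are folds and lines are 95% counting intervals. Folds run from 69.9-fold higher for Serpina3n to 1582-fold lower for Tyrobp, and the 5 lowest genes are macrophage genes.

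The culture protocol aims at a lipofibroblast-like state, and the lists of lipid genes asked how far each part of that program differed. Target genes of PPARG, the nuclear receptor that rosiglitazone activates, were mostly higher: 6 of 11 measured members were at least 1.5-fold higher and 1 was lower, with a median log2 fold of 0.80. The interval of this median over the members ran from -0.24 to 3.61 and so included 0. The lower one, Ucp2, named after its values were seen, was 3.51-fold lower over all cells but 1.24-fold higher in fibroblast-like cells alone. That median stood at percentile 100 of 10000 random lists of the same size matched on expression. Fabp4, which encodes a fatty acid binding protein, was at 145 CPM against 11.9 CPM. The lipoprotein lipase inhibitor gene Angptl4 was 7.40-fold higher (7.01 to 7.81), the pyruvate dehydrogenase kinase gene Pdk4 13.3-fold higher (10.8 to 16.6), and Plin2, which encodes a lipid droplet coat protein, 1.74-fold higher (1.67 to 1.81). Pparg itself, below the mean of 5 CPM set for comparison, was at 4.11 CPM against 3.66 CPM, a fold of 1.12 (0.975 to 1.3).

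Markers of lipofibroblasts did not move together. Of 10 measured members, 3 were higher (Lpl, Pdgfra, Plin2), 2 were lower (Gyg, Itga8) and the median log2 fold was 0.03, at percentile 82.0; in fibroblast-like cells alone it was -0.20. Pdgfra, a fibroblast receptor gene, was 2.60-fold higher (2.48 to 2.72) over all cells but had a fold of 0.781 between matched clusters 9 and 6. In contrast, Tcf21, a transcription factor gene used to mark lipofibroblasts, was at 1.18 CPM against 8.16 CPM and 6.93-fold lower (5.77 to 8.38). The mean of Tcf21 was below 5 CPM, so it is not among the 10 measured members and does not enter their median. Lipid droplet and triglyceride storage genes had a median of 0.06 (percentile 84.0), with 1 of 12 members higher (Plin2), and Dgat2, which makes triglyceride, was 2.02-fold lower (1.80 to 2.28). Genes of fatty acid oxidation had a median of 0.07 (percentile 95.7), and 4 of 21 were higher, among them Cpt1a at 2.19-fold and Ech1 at 1.95-fold. The list of fatty acid and lipoprotein uptake and export had a median of -0.25 (percentile 6.82), with Fabp4 and Lpl higher and 3 members lower; among genes with a mean of at least 20 CPM it was 0.41. No member of the fatty acid synthesis list (median -0.20, percentile 13.3) or of the cholesterol synthesis list (median -0.33, percentile 0.3) was 1.5-fold higher, and 3 of 14 and 7 of 21 were lower, including Scd2 at 2.03-fold and Insig1 at 2.12-fold. None of the 8 adipocyte markers reached the measured level, and the 11 thermogenic adipocyte genes gave 3 measured members, of which Dio2 (5.38-fold) and Ebf2 (1.88-fold) were higher. Adipoq was near the floor, with 0.128 CPM against 0.0113 CPM.

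Contractile and myofibroblast genes were lower almost throughout. Of 19 measured members, 17 were at least 1.5-fold lower and none was higher, with a median log2 fold of -1.29 (percentile 0, interval of the median -1.92 to -0.90). Acta2, the smooth muscle actin gene that marks myofibroblasts, was at 1097 CPM against 3217 CPM, 2.93-fold lower (2.91 to 2.95). Tagln was 2.45-fold lower, Tpm1 2.58-fold, Actg2 11.1-fold, Cnn1 11.7-fold and the smooth muscle myosin gene Myh11 72.3-fold (54.0 to 99).

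Genes that respond to TGF-beta, a driver of myofibroblast genes, had 11 of 15 members lower and none higher, with a median of -1.07 (percentile 0, interval -1.72 to -0.42). Ctgf was 3.49-fold lower (3.4 to 3.58) and the integrin gene Itgb5 3.55-fold (3.44 to 3.67), whereas Timp1 was at 2581 CPM against 1998 CPM. The BMP response list was lower too, with a median of -1.72 (percentile 0, interval -2.58 to -0.09), 7 of 11 members lower and none higher. This median moved to -1.08 under TMM scaling, where the measured members differ. Id1 differed little, at 79.0 CPM against 84.8 CPM, Id3 was 1.57-fold lower (1.55 to 1.59), the BMP antagonist gene Grem1 3.38-fold lower (3.3 to 3.46) and Id4 11.7-fold lower (9.45 to 14.6).

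Collagen genes split. Of 19 measured members, 10 were lower and 4 were higher, with a median of -0.92 (percentile 0). The interval of this median, -1.48 to 0.51, included 0, and the median was -0.50 without mitochondrial and ribosomal protein genes, -0.54 in cells not in cycle and -0.07 between matched clusters 9 and 6. Leaving out those genes shifts all log2 folds by only 0.041, so most of the first move came from the members that passed the 5 CPM filter. Col1a1 was at 471 CPM against 2399 CPM, 5.10-fold lower (5.05 to 5.14), Col1a2 2.78-fold lower (2.76 to 2.80), Col3a1 2.74-fold lower (2.70 to 2.79) and Col14a1 33.2-fold lower (26 to 42.9). Col15a1 and all 3 measured collagen VI genes were higher, the latter named after their values were seen: Col6a1 by 3.26-fold, Col6a2 by 5.38-fold and Col6a3 by 2.82-fold. The basement membrane collagen gene Col4a1 was at 607 CPM against 537 CPM. Among other matrix genes 14 of 30 were lower and 4 higher, with a median of -0.43 (percentile 0): Sparc was 2.30-fold lower, Thbs1 2.63-fold lower and Lum 120-fold lower (76.6 to 200), while Mgp, which encodes a calcification inhibitor, was 2.74-fold higher (2.73 to 2.76). Lum, Dcn and Col14a1 were leading genes of control cluster 4, 14.6% of that library, so their folds over all cells may rest largely on that cluster. Matrix proteases and inhibitors had 4 of 14 members higher, Mmp3 among them, and 6 lower, including Timp3 at 12.7-fold (12.4 to 13), with a median of -0.25 (percentile 6.99), which was 0.13 among genes with a mean of at least 20 CPM.

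**Figure D2:**
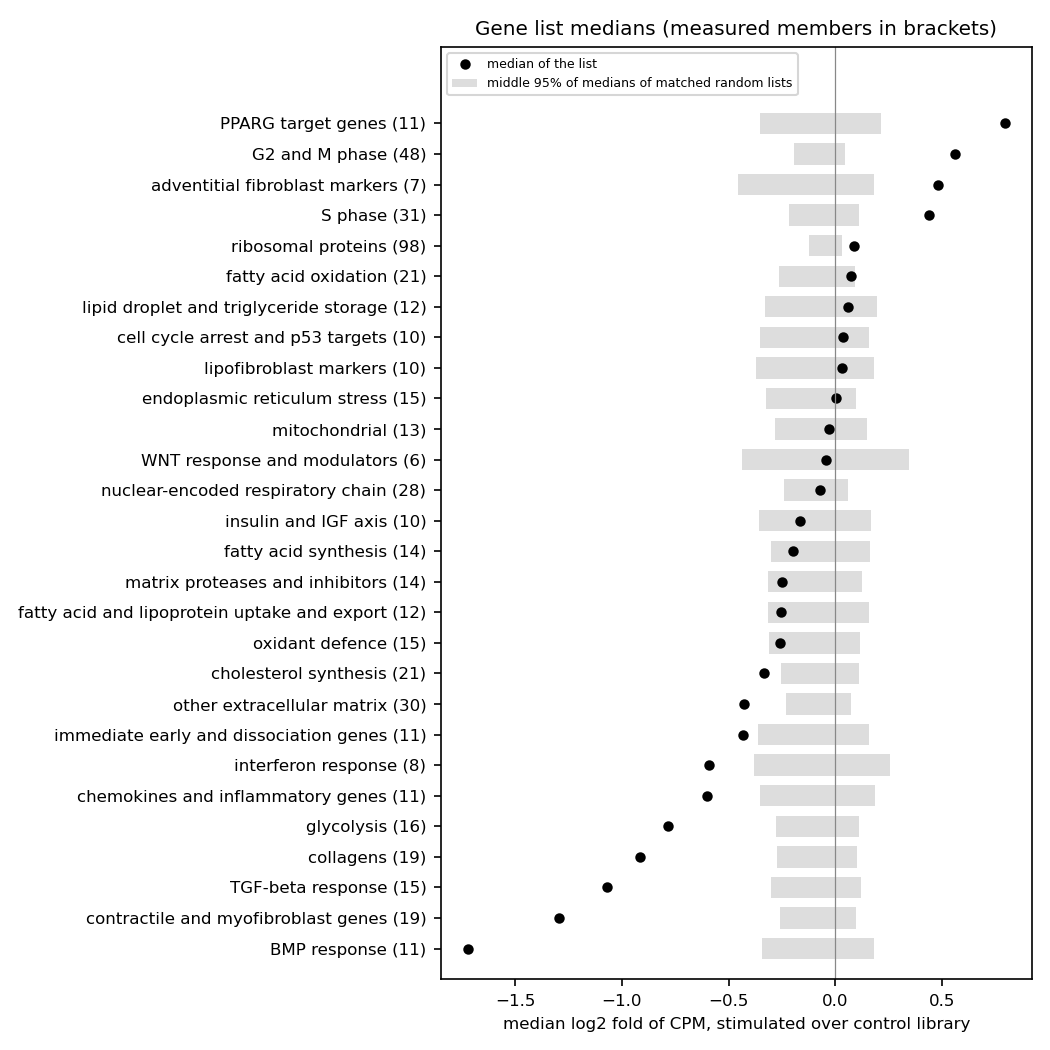
Median log2 fold of CPM, stimulated over control library, of each program list with at least 5 measured members; points are list medians and grey bars span the middle 95% of medians of matched random lists. BMP response (-1.72) and contractile genes (-1.29) lie lowest, and PPARG targets (0.80) and G2 and M phase genes (0.56) highest. Under TMM scaling, where the measured BMP members differ, the lowest lists stand in the other order (-1.08 and -1.19). Among genes with a mean of at least 20 CPM, adventitial fibroblast markers (0.84) stand above PPARG targets (0.80).

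Glycolysis genes were lower, with 12 of 16 members at least 1.5-fold lower, 1 higher and a median of -0.78 (percentile 0). The lactate exporter gene Slc16a3 was 4.46-fold lower (4.25 to 4.69), Gapdh 1.80-fold, Aldoa 1.74-fold and Pkm 1.44-fold; the member that was higher, Pgk1, named after its values were seen, was at 92.4 CPM against 31.3 CPM and shares 27.3% of its 3′ end windows with another gene. Gapdh shares 57.4%. Nuclear-encoded respiratory chain genes had no member past 1.5-fold in either direction (28 measured, median -0.07, percentile 52.4), and mitochondrial genes (13 measured, median -0.03, percentile 54.7) had 1 higher, mt-Nd4l. Ribosomal protein genes had a median of 0.09 (percentile 100), with 95 of 98 members between these bounds.

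Cell cycle genes were higher over all cells, but not in every matched pair of clusters. In the S phase list 8 of 31 members were higher and none lower (median 0.44, percentile 100), and in the G2 and M phase list 21 of 48 were higher and none lower (median 0.56, percentile 100). Mki67 was 1.71-fold higher (1.61 to 1.81) and Top2a 1.59-fold higher (1.53 to 1.65). At 5000 UMIs per cell, 25.2% of stimulated cells (24.2 to 26.2%, 6708 cells) and 15.2% of control cells (14.1 to 16.3%, 4077 cells) carried at least 5 UMIs of 12 cycling genes, and without thinning these shares were 44.4% and 28.9%. In the count at 5000 UMIs, 965 stimulated and 358 control cells lay within 1 UMI of the threshold, and the share depends on depth and threshold, though it was higher in the stimulated library at each setting tried. Whether free RNA in the droplets adds to it is open. Between the matched clusters 3 and 1, both led by cycling genes, the medians were -0.30 for S phase and -0.27 for G2 and M phase. Mki67 and Top2a had folds of 0.893 and 0.795 there. This pair sets cycling cells against cycling cells, so it does not bear on how many cells cycle. In clusters 4 and 7 the medians were 1.35 and 2.71. The list of cell cycle arrest and p53 targets had a median of 0.03 (percentile 83.3), with Cdkn2a 1.64-fold higher (1.60 to 1.69) and Cdkn1a at 403 CPM against 399 CPM.

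Secreted signals and stress genes moved in several directions. In the insulin and IGF axis 3 of 10 members were lower and 1 higher (median -0.16, percentile 26.2), with Igf1 and Igfbp2 (62.9-fold lower, 48.6 to 82.8) far apart from Igfbp7 (1.46-fold lower) and Igfbp6 (1.40-fold higher). Igfbp2 was a leading gene of control cluster 4, so its fold carries the limit given for Lum. Chemokines and inflammatory genes had 6 of 11 members lower and 1 higher (median -0.60, percentile 0.09). The interval of this median, -3.26 to 0.36, included 0. Saa3 was lower, Cxcl12 1.51-fold lower and Ccl7 1.55-fold lower, the last reversed (fold 1.5) between matched clusters 9 and 6. Interferon response genes had 4 of 8 members lower and 1 higher (median -0.59, percentile 0.25). The median was -0.19 without mitochondrial and ribosomal protein genes, mostly through the members that passed the 5 CPM filter, since all log2 folds shift by only 0.041. It was 0.03 between the largest matched clusters of the libraries, so no direction is given for this list. Ifi27l2a was 6.48-fold lower (5.73 to 7.34) and Ifitm3 was at 1278 CPM against 978 CPM. Oxidant defence genes gave 3 higher and 4 lower of 15 (median -0.26, percentile 5.93), and the 2 metallothionein genes were the most abundant of them: Mt2 was 7.25-fold higher (7.20 to 7.30) and Mt1 4.73-fold higher (4.71 to 4.75). Endoplasmic reticulum stress genes had a median of 0.00 (percentile 83.9), with 4 of 15 lower, among them Trib3 at 3.76-fold. Immediate early and dissociation genes had a median of -0.43 (percentile 1.01), which was 0.06 among genes with a mean of at least 20 CPM, and WNT response genes one of -0.04 (percentile 49.2), where Sfrp2 was 19.6-fold higher (14.8 to 26.6) over all cells with a fold of 0.787 between clusters 9 and 6.

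Markers of fibroblast subtypes and of other cell types were checked in the same way. Adventitial fibroblast markers had 3 of 7 members higher, Ly6a at 6.78-fold (6.58 to 6.99) among them, and 2 lower, with a median of 0.48 (percentile 99.9). The interval of this median ran from -5.05 to 2.80, and without genes with shared 3′ ends the median was 0.15, so no direction is given for this list. Of 3 measured alveolar fibroblast markers Itga8 was 3.03-fold lower, Npnt was at 34.1 CPM against 36.7 CPM and Limch1 at 32.3 CPM against 39.8 CPM. In fibroblast-like cells alone Limch1 was 5.58-fold and Npnt 1.35-fold lower, but that class leaves out stimulated cluster 6, where Limch1 is a leading gene, and keeps its control counterpart 9. Between matched clusters no fold of Limch1 was as large, with log2 folds from -1.24 (clusters 3 and 1) to 0.10 (clusters 9 and 6). In the osteogenic and chondrogenic list the bone matrix gene Spp1 was at 3497 CPM against 400 CPM and Sox9, a cartilage transcription factor gene, was 3.70-fold higher (3.47 to 3.95). Of the fibroblast markers 5 of 7 were lower and 2 higher (median -1.48), of the smooth muscle markers 4 of 5 were lower (median -3.48), and of the macrophage markers 7 of 7 were lower (median -8.29). Pericyte and endothelial markers had no member past 1.5-fold among 2 and 1 measured, mesothelial markers had Msln 9.69-fold higher (8.05 to 11.8) among 2 measured, and no epithelial, lymphocyte, neutrophil, glial or erythroid marker reached the measured level.

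The next question was whether these differences lay in few cells or in most. With each cell thinned to 5000 UMIs, 4077 control and 6708 stimulated cells remained, while 626 and 760 were too shallow. The contractile list summed to a median of 54 UMIs per control cell (quartiles 36 and 82) and 20 per stimulated cell (quartiles 13 and 31). Below the control library's lowest 5%, that is under 18 UMIs, lay 41.1% of stimulated cells (39.9 to 42.3%), and 0.119% (0.0515 to 0.235%) lay above the control 95th percentile. The PPARG target list was far less abundant, with a median of 2 UMIs per stimulated cell (quartiles 1 and 3) and 1 per control cell (quartiles 0 and 1). Above the control 95th percentile of 3 UMIs lay 22.0% of stimulated cells (21.1 to 23.1%), against 3.88% of control cells (3.3 to 4.51%). The control share includes macrophage-like cells, 131 at this depth, whose median sum was 5 UMIs. Control cluster 2, the largest fibroblast-like one, had a median of 1, so the control share is not one of fibroblasts alone. Across the cells of a library the 2 sums had a Spearman correlation of -0.03 in the control and 0.06 in the stimulated library. These values are given as a description since cells are not replicates. The PPARG target sum was 0 in 43.9% of control and 14.0% of stimulated cells, and counts this low pull a correlation toward 0. The values therefore cannot show whether the 2 programs are related.

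**Figure D3:**
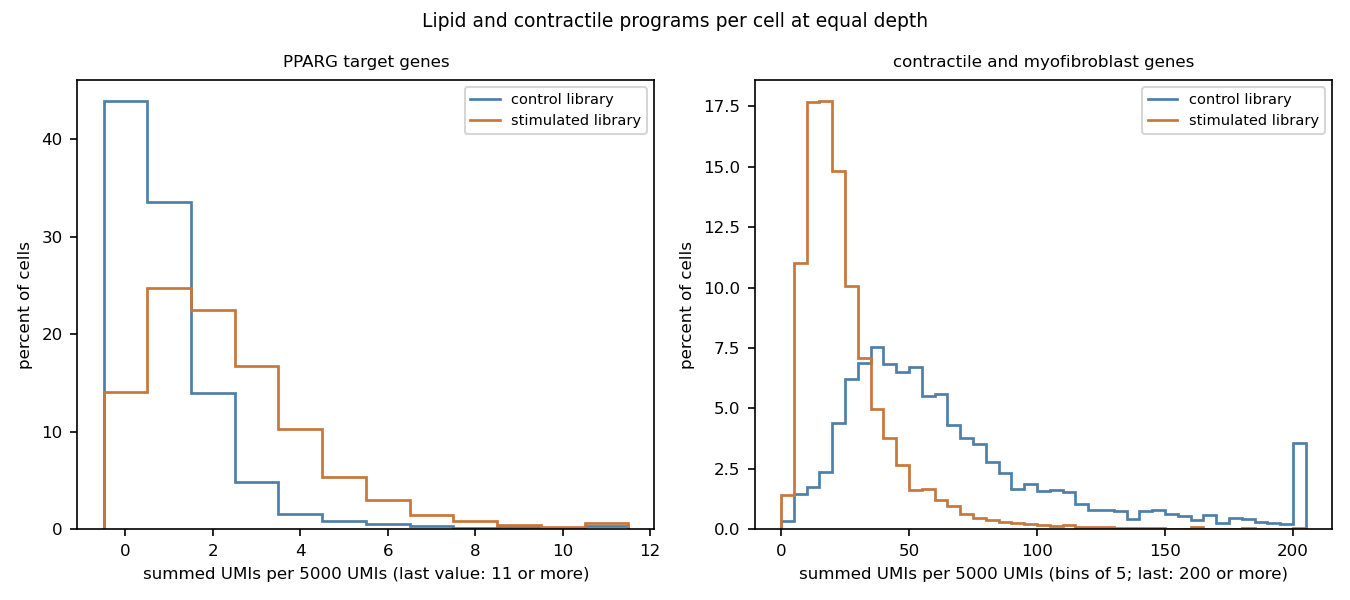
Percent of cells by summed UMIs of the PPARG target list and of the contractile list, each cell thinned to 5000 UMIs; lines are the control and the stimulated library. The contractile sum has a median of 54 UMIs in control and 20 in stimulated cells, and the PPARG target sum 1 and 2.

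Shares of cells with a UMI at this depth followed the CPM. Fabp4 was found in 36.6% of stimulated cells (35.4 to 37.7%) and 4.59% of control cells (3.96 to 5.27%), and without thinning in 59.8% and 13.1%. In the same order, Angptl4 was found in 41.8% and 6.55% (unthinned 71.1% and 18.8%), Plin2 in 25.9% and 17.3% (53.8% and 42.5%) and Lpl in 5.83% and 2.23% (14.1% and 6.4%). Pparg was found in 2.07% and 1.77% (6.16% and 6.53%). Acta2 was found in 83.5% of stimulated and 98.3% of control cells (94.9% and 99.8%), Tagln in 83.3% and 97.5% (91.7% and 98.5%), Col1a1 in 80.7% and 96.7% (93.5% and 96.5%) and Col3a1 in 47.3% and 74.7% (72.9% and 87.5%). Tcf21 was found in 0.492% and 3.66% (1.74% and 11.6%), Pdgfra in 28.7% and 11.4% (56.0% and 30.4%), Fgf10 in 3.46% and 2.65% (9.43% and 7.63%), Postn in 4.32% and 11% (10.8% and 26.6%), and Eln in 0.745% and 2.53% (2.04% and 5.15%). Id1 was found in 27.9% and 28.6% (52.4% and 53.9%), Id3 in 70.9% and 78.0% (87.6% and 89.0%), Mki67 in 12.6% and 6.74% (27.2% and 16.4%) and Top2a in 20.3% and 12.5% (35.6% and 22.4%). Of 4077 control cells 0 held an Adipoq UMI at 5000 UMIs, for which the exact binomial upper limit is 0.0904% of cells with a UMI, and 0.0745% of stimulated cells held one (unthinned 0.134% of stimulated and 0.0213% of control cells). Cd36 was found in 0.0596% and 1.91% (0.0803% and 2.93%).

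Free RNA limits how such shares can be read. In 131 control macrophage-like cells at 5000 UMIs, which should lack fibroblast transcripts, 61.8% had a Col1a1 UMI, 89.3% an Acta2 UMI, 58.8% a Tagln UMI and 30.5% a Col3a1 UMI. Id3 was found in 29.8% of them, Id1 in 18.3%, Pdgfra and Postn in 3.05% each, Angptl4 in 3.82%, Fgf10 and Eln in 0.763% each, and Tcf21 in none. Mki67 (10.7%) and Top2a (16.8%) were at least as frequent there as in the control library at large, so the control shares of these genes are not above this level. The same held for Pparg (3.05%), on 4 of 131 cells (0.838 to 7.63%). Whether macrophage-like cells cycle or express Pparg themselves was not tested, and doublets remain. None of these values can thus be read as free RNA alone. The macrophage-like cells had a median of 10591 UMIs before thinning, against 21323 for control fibroblast-like cells, and too few were seen in the stimulated library to give its background. Macrophages themselves express lipid genes, so Plin2 (46.6%), Fabp4 (25.2%), Lpl (6.87%) and Cd36 (56.5%) in these cells cannot be read as background alone. The shares of Plin2, Lpl and Cd36 in both libraries lie below these. Among fibroblast-like cells Cd36 was found in 0.108% of control and 0.0657% of stimulated cells. In mesothelial-like cells Fabp4 was found in 3.57% of 56 control and 4.35% of 23 stimulated cells, Lpl in 12.5% and 52.2%, and Angptl4 in 10.7% and 34.8%, so the shares of Lpl and Angptl4 are not particular to fibroblast-like cells. In fibroblast-like cells alone Fabp4 was found in 38.5% of the stimulated and 3.85% of the control cells.

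**Figure D4:**
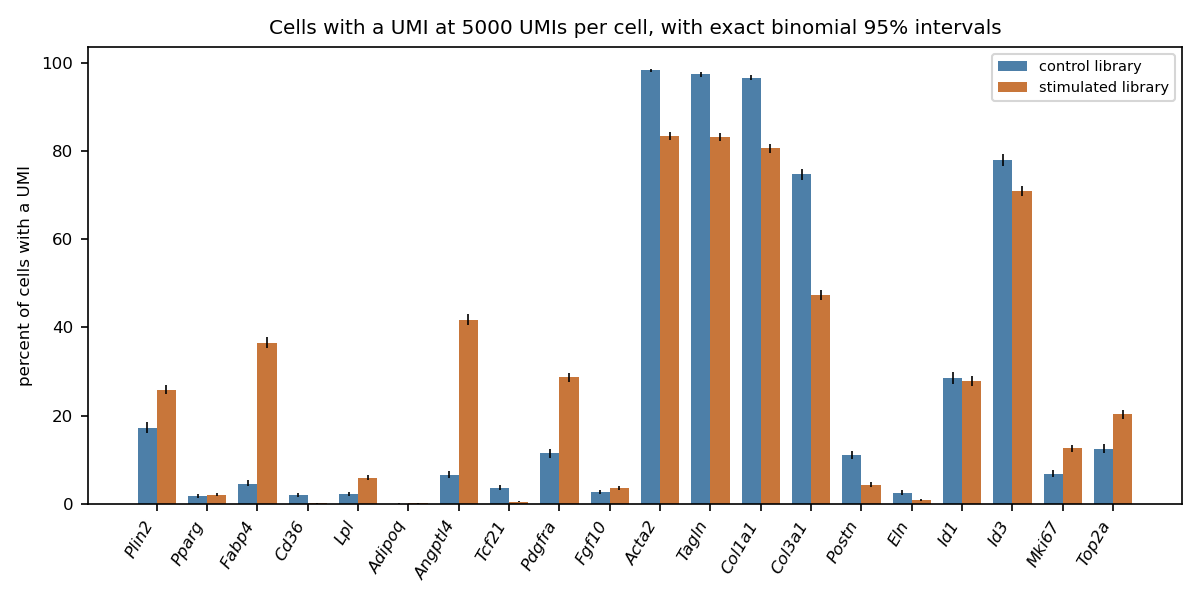
Percent of cells with at least 1 UMI of each gene after thinning to 5000 UMIs per cell; bars are the control and the stimulated library and lines are exact binomial 95% intervals. Fabp4 (36.6% against 4.59%) and Angptl4 (41.8% against 6.55%) stand higher in the stimulated library, and Col3a1 (47.3% against 74.7%) lower.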

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

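The comparisons between pairs of matched clusters, without macrophage-like and shallow clusters, and without genes with shared 3′ ends were chosen after the data had been seen. No paired analysis was possible because each group is 1 library. The counts of 290 genes at least 2-fold higher and 444 lower stayed within 1.5 times under every scaling, cell filter and weighting set beforehand. They followed the expression filter, as more or fewer genes enter: 530 and 878 at a mean of at least 1 CPM, and 127 and 209 at 20 CPM. Without a filter and with 0.5 CPM added, which changes both together, they were 540 and 943. Leaving out no cell as a doublet changed nothing, as the caller's marks were not used, and says nothing about stability. Without macrophage-like and shallow clusters the counts were 293 and 445, and without shared 3′ ends 270 and 440. Of the alternatives set beforehand, that of fibroblast-like cells alone turned Ucp2 from 3.51-fold lower to 1.24-fold higher. It left Cd36, 18.9-fold lower over all cells but with a mean below the 5 CPM set for comparison, at a fold of 1.01. No list median past 1.5-fold changed sign under the alternatives set beforehand. Lists nearer 0 did: fatty acid uptake and export (0.411), matrix proteases (0.132), immediate early genes (0.059) and lipofibroblast markers (-0.109) at 20 CPM, lipofibroblast markers also in fibroblast-like cells (-0.201), cells not in cycle (-0.031) and without mitochondrial and ribosomal protein genes (-0.068), WNT response and mitochondrial genes under TMM (0.059 and 0.077) and median of ratios (0.044 and 0.061), and endoplasmic reticulum stress, near 0 throughout (-0.052 to 0.107). The BMP median, below the contractile one over all cells, lay above it under TMM (-1.083 against -1.190), without mitochondrial and ribosomal protein genes (-1.146 against -1.253), with each cell weighted equally (-1.177 against -1.380) and at 20 CPM (-1.187 against -1.294). The respiratory chain median was 0.035 under TMM scaling and 0.020 under median of ratios, through the shift of all folds. The ribosomal median was 0.194 and 0.178 under these, 0.133 in cells not in cycle and 0.153 with each cell weighted equally.

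Within matched clusters more moved; why was not tested. In clusters 2 and 0 the medians of interferon response (0.033), G2 and M phase (0.175) and ribosomal proteins (0.023) differed, and interferon response reversed. In the cycling clusters 3 and 1 the medians of S phase (-0.298) and of G2 and M phase (-0.267) changed sign, and the folds of Clspn (0.948), Mki67 (0.893) and Top2a (0.795) reversed. Both clusters are led by cycling genes, so this pair leaves out any difference in how many cells cycle. In clusters 4 and 7, 553 genes were higher, and the medians were 1.347 for S phase, 2.714 for G2 and M phase, 0.447 for fatty acid oxidation, -0.075 for cholesterol synthesis, 0.195 for the respiratory chain, -0.504 for glycolysis, -0.472 for mitochondrial and -0.086 for ribosomal genes. In clusters 9 and 6 the medians were -0.199 for S phase, 0.063 for G2 and M phase and 0.278 for ribosomal genes, those of collagens (-0.072) and interferon response (-0.103) came close to 0, and oxidant defence (0.015) and lipid droplet genes (-0.098) changed sign. The WNT median was -1.475 there, 0.932 in clusters 2 and 0, 0.079 in 3 and 1 and 0.926 in 4 and 7. Lipofibroblast markers (-0.301 in 4 and 7, -0.173 in 9 and 6), endoplasmic reticulum stress (-0.206 in 3 and 1) and arrest and p53 genes (-0.009 in 2 and 0, -0.019 in 3 and 1) also changed sign. In clusters 9 and 6 the folds of Timp2 (1.07), Ccl7 (1.5), Sfrp1 (0.509), Sfrp2 (0.787) and Pdgfra (0.781) reversed.

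Cycling shares moved with depth and threshold, which set how many UMIs can be seen: control 8.47% and stimulated 13.7% at 3000 UMIs, 21.6% and 36.3% at 8000 UMIs, 22.5% and 37.8% at 3 UMIs or more, 5.76% and 8.50% at 10 or more. The share of stimulated cells above the control 95th percentile of PPARG targets was 17.8% at 3000 UMIs and 30.9% at 8000 UMIs. For 20 of 21 genes the library with the larger share of cells with a UMI was the same at 3000, 5000 and 8000 UMIs; the exception was Id1. Fibroblast-like cells were 78.9% of control and 75.3% of stimulated cells at resolution 1.0, where 3.36% of stimulated and 0% of control cells were smooth muscle-like, and 64.7% of control cells with each library clustered alone, where no stimulated cell (0%) was mesothelial-like; the cause was not tested.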

Other observations

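The matching of clusters and the sums over copies of a gene were chosen after the data had been seen. The predictions of the tests were written before their values were known. For the test of shared 3′ ends and the selenoprotein test, the rule that turns the value into an outcome was edited after the value was known. Clusters of the 2 libraries were matched by the Spearman correlation, across 3565 genes, of how each differs from the rest of its own library; genes are not independent replicates. There were 4 mutual best pairs. Clusters 2 and 0 were the largest (rho = 0.79), clusters 3 and 1 had cycling genes in the lead (rho = 0.874), clusters 4 and 7 both had Ctsl and Hspa5 among their leading genes (rho = 0.795), and clusters 9 and 6 both had Hsd3b6 and Limch1 (rho = 0.598). Of the 290 genes at least 2-fold higher over all cells 228 were at least 1.5-fold higher in each of the 4 pairs, and of the 444 lower 388 were lower in each. The pairs hold most of the cells behind these folds, so this describes how even the folds are and is no separate check, and how much of the macrophage genes in fibroblast clusters is free RNA was not tested. The contractile list's median lay between -1.31 and -1.09 over the pairs, the TGF-beta list's between -1.40 and -1.08 and the PPARG target list's between 0.97 and 1.14.

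Fkbp5, Sgk1, Errfi1, Pdk4 and Serpina3n, which respond to glucocorticoids in many cells, were higher in the stimulated library, Sgk1 at 318 CPM against 83.9 CPM and Errfi1 at 244 CPM against 64.1 CPM. The hypothesis that targets of the glucocorticoid receptor were higher as a set was tested on 10 other targets. Of the 6 measured, all 6 were at least 1.5-fold higher, with a median log2 fold of 1.65 (interval of the median 1.02 to 8.59) at percentile 99.99 of matched random lists. Klf9 was 3.06-fold higher, Per1 3.23-fold, Tsc22d3 2.61-fold and Ampd3 3.52-fold. Zbtb16, with no UMI in the control library, was at least 386-fold higher against a floor of 3 counts over that library. This bound is the upper end of the interval of the median, which spans all 6 members. The result is consistent with a difference in glucocorticoid receptor signalling, but these genes may answer to other signals too, and the labels name no glucocorticoid.

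Several genes induced by low oxygen (Slc16a3, Ndufa4l2, Vegfa, Ero1l, Plod2, Pfkfb3 and Hk2) were lower in the stimulated library. The hypothesis that hypoxia-responsive genes were lower as a set was tested on 13 others, all measured. Of these 10 were at least 1.5-fold lower and none higher, with a median log2 fold of -1.315 (interval -1.66 to -0.58) at percentile 0. Higd1a was 3.16-fold lower, Bnip3 3.24-fold and Fam162a 2.81-fold, whereas Adm was 1.24-fold higher. Oxygen supply, cell density and growth signals may each set these genes, and the data do not separate them.

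Sepp1, which encodes a selenoprotein, was 4.23-fold higher. The hypothesis that selenium-sensitive transcripts were higher as a set stayed undecided: 6 other selenoprotein genes had a median log2 fold of 0.081, with an interval of the median from -1.55 to 0.72, and went both ways. Msrb1 was 2.93-fold lower and 2700094K13Rik 1.64-fold higher. The bound written beforehand, a median of at most 0.26, would have counted against the hypothesis, but members that go both ways leave a median near 0 without weight.

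Genes with near-identical copies differed several-fold between the libraries. Of 124 compared genes with mostly shared 3′ ends 19.4% (exact binomial interval 12.8 to 27.4%) were at least 2-fold apart, against 8.54% of expression-matched genes with unique ends, a ratio of 2.27 (1.5 to 3.21). For the 24 genes that were 2-fold apart, the median fold in each matched pair of clusters and, for 17 of them, in mesothelial-like cells was within 1.34 times that over all cells. For these genes as a set this argues against a difference confined to particular cell states. The genes were picked by their folds over all cells, most of which lie in the pairs, and a median says nothing about single genes. Summed with its copy Rpl41, Gm10076 went from 3.62-fold higher to 1.04-fold. Nme2 with Gm20390 was 11.6-fold higher, Hist1h2ap with Hist1h2ao 14.6-fold and Pgk1 with Pgk1-rs7 2.98-fold. Gm20390, Hist1h2ao and Pgk1-rs7 were at no more than 1.37 CPM in either library, so adding them could hardly change a fold. These 3 sums therefore cannot show whether shared reads set the folds of Nme2, Hist1h2ap and Pgk1. Reads shared between copies and counted differently in the 2 libraries are a candidate explanation, and a response common to all cells, read length and reference were not tested.

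Every large fibroblast-like cluster came almost wholly from 1 library. Donors of different sex are argued against, since Xist was at 921 CPM in the stimulated and 797 CPM in the control library, a ratio of 1.16, and 4 Y-linked genes had 0 UMIs in both. Without genes with shared 3′ ends 0.854% of cells sat in clusters with at least 10% of their cells from each library. With every cell thinned to 5000 UMIs it was 2.39%, and 6.01% in the joint clustering. Thinning leaves out cells under 5000 UMIs, so these 2 values are over different cells and the drop between them is not read. The shares of 0.854% and 2.39% are themselves small, which argues against shared ends or depth as the whole cause. The stimulation itself, and any difference in library preparation, remain open, since each group is 1 library.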
